A study of Mus musculus with 6 samples.

How the data were processed

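The series compares RNA from mouse E14 embryonic stem cells with a CRISPR/Cas9 knock-out of Dot1l with RNA from WT cells, 3 samples each, by sequencing of total RNA libraries. Per the submitters' processing notes, the authors aligned reads with HISAT2 2.1.0 to mm10, counted them with featureCounts 2.0.0 and tested them with DESeq2, whose version is not given in the sources used here. How the counting treated strand and reads that map to several places is not stated in these sources, so genes with near-identical copies, overlapping genes and repeated elements carry that uncertainty. Size factors, filters and the model formula are not given in the sources used here either.

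The deposited files are 3 tables of the authors' own comparison of the genotypes, for 19571 genes, 938 TE subfamilies and 26255 single TE copies, with no columns per sample. Per the file headers, the mean signal is the average over all libraries of read counts that the authors divided by size factors. The effect is a log2 fold change with its standard error, per the file headers. Per the file headers, the score is the authors' Wald statistic, and it was checked to equal the fold change divided by its error. The p-value is the authors' Wald p with its Benjamini-Hochberg adjustment, per the file headers; recomputing the adjustment over the entries that have a p gave the same values. There were 7 genes, 2 subfamilies and 51 copies without a p, and the lowest mean was 4.79 among genes, 4.62 among subfamilies and 3.61 among copies. Since values per sample were not analysed here, library depths and the spread of single samples are unknown, and no interval for counting error was computed.

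Tests planned before the data were examined were an edgeR or limma fit of the samples, with the authors' own comparison only where no values per sample exist. That last case applied, so all calls come from the DESeq2 results the authors deposited, at an adjusted p under 0.05. The planned requirement that all 3 KO values lie on one side of the 3 WT values could not be applied. For the gene lists and TE lists, the planned rotation test needs values per sample, so cameraPR of limma 3.58.1 in R 4.3.3 was run on the authors' Wald statistics with a preset correlation of 0.01. It asks whether members of a list differ from all other entries of the table. An estimated correlation needs values per sample as well; with a preset correlation of 0.05, 4 of the 9 gene lists called and 3 of the 4 TE lists called still passed. Lists needed at least 5 tested members among genes and 3 among TEs, and Benjamini-Hochberg adjustment ran over the gene lists and over the TE lists separately. Each list also received the number of members past the threshold adjusted over the list alone, and the place of its median among 10000 random lists drawn from the same 20 bins of mean count.

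The direction of the fold changes is not stated by the files and the level of Dot1l does not settle it. A positive value was read as higher in Dot1l KO on the strength of published work on MERVL in such cells, and all directions rest on that reading.

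The genes to be named were fixed by rule. The rule took Dot1l, the 6 largest rises and 6 largest falls past the threshold with a mean count of at least 50, leaving out predicted models (Gm followed by digits, Rik clones and other clone names), and the 2 members of each list with the smallest p, predicted models included. Among TE subfamilies it took the 5 largest changes in each direction past the threshold and 6 fixed elements, MERVL-int, MT2_Mm, IAPEz-int, L1Md_A, L1Md_T and MMERVK10C-int. Among copies it took the 3 largest changes in each direction past the threshold with a mean count of at least 50, so copies without a p were not eligible. Other genes and elements with values in the text were chosen after their values were seen. The value of 1 list member is not reported here. Gene coordinates are those of GENCODE mouse release M21 (GRCm38, the assembly of mm10), matched by symbol; all 19571 symbols matched, 39 of them to several loci, of which the one listed first was used.

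From the mean and the fold change, the mean of each group was implied under equal group sizes. The lowest implied levels form steps, and a level under 0.25 was taken as a group without reads. Folds against such a group are given only as a bound, with the group set to a floor of 3 reads, taken as 1 normalized count per library. The fitted fold is no bound. The bound takes the level of the other group without its error, so it is not the lower end of a confidence interval. Alternatives that could be run were a stricter threshold of 0.01, a log2 fold change of at least 1, centring on the median of the table or within 20 bins of mean count, a mean count of at least 50, scaling of the Wald statistics by their interquartile range, Bonferroni adjustment, and cameraPR on ranks, with a preset correlation of 0.05 or on centred statistics. The median log2 fold change was -0.02 over genes, -0.05 over subfamilies and 0.02 over copies. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

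The steps were tested on simulated data before use. For the comparison of Dot1l KO with WT, fold changes were drawn for 19571 genes with the real means and errors, with 200 genes changed. At a log2 change of 1, 15 of 67 were recovered (22.4%), at 2, 50 of 67 (74.6%), and at 4, 60 of 66 (90.9%), and 3 of 19371 unchanged genes were called. With a trend in mean count like the observed one, 25 unchanged genes were called, and 7 after centring within bins. Of 100 lists of 20 genes shifted by 2 in the Wald statistic, 100 were called, and of 200 unshifted lists, 1. The noise was drawn independently for each gene, whereas the real gene statistics were wider (ratio 1.30) and members of a list may be correlated. The false calls here are therefore no estimate of those in the data. Recovery of lists with a mean shift smaller than 2 was not simulated.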

Results

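RNA was sequenced from mouse E14 embryonic stem cells, a male line that grows without feeder cells, kept in serum with LIF. The comparison sets 3 samples of Dot1l knock-out (KO) cells made with CRISPR/Cas9 against 3 samples of wild-type (WT) cells, all labelled day 14. What that day is counted from is not stated in the sources used here, so it is not read as a time point. Dot1l encodes the methyltransferase of lysine 79 of histone H3, a mark found along transcribed genes. The question is which genes and which transposable elements (TEs) differ in RNA level between the genotypes. There are 3 tables, one of 19571 genes, one of 938 TE subfamilies and one of 26255 single TE copies, each giving the mean normalized count over all libraries, the log2 fold change with its standard error (SE), and the p-value.

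The means of the gene table sum to about 36042600 normalized counts, those of the subfamily table to 888505 and those of the copy table to 482719. The tables carry no values per sample, so the depth of each library is unknown, and nothing says whether replicates came from separate cultures or clones; the p-values measure the spread between these samples. The tables do not state which genotype a positive fold change favours. It was read as higher in Dot1l KO, because published work describes the endogenous retrovirus MERVL as repressed by Dot1l in embryonic stem cells. The direction of MERVL is therefore not independent evidence here, and if the sign were the other way, every direction given would reverse. Genes were taken from lists fixed in advance and from a rule on effect size, and further list members given as examples were chosen after their values were seen.

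Dot1l itself (chromosome 10, 80755206 to 80795461 in mm10) did not pass the test at the RNA level. In the authors' deposited table its log2 fold change was -0.16 ± 0.25 (SE), adjusted p = 0.845, at a mean of 5761 normalized counts, with a 95% interval of -0.66 to 0.33. A frameshift deletion need not lower the RNA, so this level does not settle which samples lack the protein. The list of H3K79 methylation partners, with the proteins that bind Dot1l or work with it in elongation, held 18 tested genes, and 0 passed the test of DESeq2; at an unadjusted p under 0.05 it had 1 higher and 0 lower. Its lowest p-values belonged to Mllt3 (chromosome 4, 87769925 to 88033364), which encodes the Dot1l partner AF9, and to Skp1a (chromosome 11, 52231995 to 52246858). The authors' deposited table gives Mllt3 0.99 ± 0.38 with adjusted p = 0.103 and Skp1a -0.58 ± 0.31 with adjusted p = 0.331. The list had a median log2 fold change of 0.02, camera gave adjusted p = 0.914, and 0 passed when adjusted over the list alone. Against random lists matched on mean count, whose median was -0.18, the list's median lay at percentile 98.3.

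Far more genes rose than fell in Dot1l KO. Among genes with a mean count of at least 50, predicted models left out, the largest rises belonged to the X-linked lymphocyte-regulated (Xlr) cluster, a multicopy family active in germ cells and lymphocytes, and to Usp17l genes, deubiquitinases transcribed in the 2-cell embryo. Among the largest falls by the same rule were Ifitm3, an interferon-inducible membrane protein marking early germ cells, the Wnt target Sp5, the aspartic protease Napsa and the neural and eye regulator Pax6. In all, 1044 genes were higher and 244 lower at an adjusted p under 0.05, which is 6.58% of the genes, and 81.1% of the calls were higher. Without adjustment, 2078 were higher and 1085 lower.

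The authors' deposited table gives the following log2 fold changes for the X chromosome: Xlr4b (73214333 to 73222453) 8.20 ± 1.11, Xlr5b (73148796 to 73158872) 7.85 ± 0.96, Xlr5a (73107635 to 73292976) 6.89 ± 0.72 and Xlr5c (73282896 to 73292976) 6.85 ± 0.90. On chromosome 7, the authors' deposited table has Usp17le (104768049 to 104777470) at 7.60 ± 0.86 and Usp17lb (104840257 to 104842603) at 6.84 ± 0.83. These 6 genes had mean counts from 78.4 to 132.4 in the authors' deposited table, with adjusted p from 1.82e-18 to 4.95e-11. They have near-identical copies, and the annotated spans of Xlr5a and Xlr5c overlap; how the counting treated reads that map to several places is not stated, so their single values are uncertain.

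Falls were smaller. Ifitm3 (chromosome 7, 141009586 to 141010770) fell by 3.34 ± 0.46 on the log2 scale in the authors' deposited table, from a mean of 5153 over all libraries, adjusted p = 8.63e-11. Sp5 (chromosome 2, 70474923 to 70477729) stood at -3.33 ± 0.64 in the authors' deposited table and Napsa (chromosome 7, 44572380 to 44586862) at -3.02 ± 0.60. For the T-cell receptor segment Trav5-2 (chromosome 14, 53614945 to 53615224), annotated as a pseudogene, the authors' deposited table has -2.95 ± 0.52. Pax6 (chromosome 2, 105668900 to 105697364) fell by 2.79 ± 0.44 in the authors' deposited table, adjusted p = 5.29e-08, and Mirg, an imprinted non-coding RNA described with its domain, by 2.65 ± 0.53.

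The excess of rises lay among weakly expressed genes. Of the genes below the median mean count of 278, 904 were higher and 58 lower; of those at or above it, 140 were higher and 186 lower. The median log2 fold change went from 0.64 in the lowest of 20 bins of mean count to -0.20 in the highest. When the fold changes were centred within those bins, 732 of the 1044 rises (70.1%) and 132 of the 244 falls (54.1%) were still called. At a mean count of at least 50, 517 genes were higher and 220 lower.

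**Figure D1:**
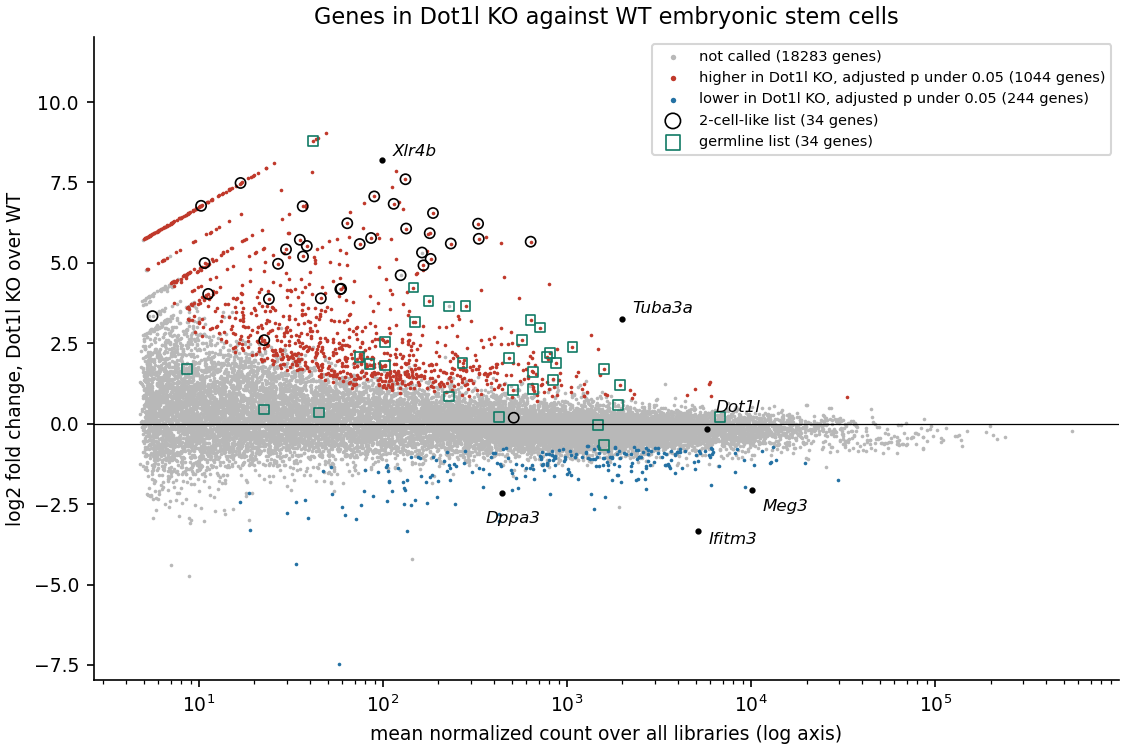
Log2 fold change (Dot1l KO over WT, authors' deposited table) against mean normalized count on a log axis for all 19571 genes, with the 1044 genes called higher in red, the 244 called lower in blue, and the 34 genes of the 2-cell-like list and 34 of the germline list ringed. Of the genes called higher, 904 lie below the median mean count of 278.

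Genes of the 2-cell-like state rose together. This state, in which a few stem cells switch on the transcripts of the 2-cell embryo, is marked by the telomere regulator Zscan4, by the transcription factor Dux and by MERVL. Of the 34 tested members, 29 rose and 0 fell, and 33 were higher when adjusted over the list alone. The median log2 fold change was 5.56, or 5.37 with the 2 members without WT reads placed at their bound, where the highest of 10000 random lists matched on mean count reached 0.94 (camera, adjusted p = 1.36e-55). Zscan4f (chromosome 7, 11397915 to 11402318) rose by 6.07 ± 0.63 and Gm21761, a predicted gene on chromosome 13 (119912095 to 119929272), by 5.66 ± 0.53 in the authors' deposited table. Zscan4a at 5.92 ± 1.95 and Zscan4d at 6.22 ± 1.31 passed too. Zscan4b at 4.18 ± 1.97, Zscan4c at 5.32 ± 2.08 and Zscan4e at 4.62 ± 2.16 did not pass, in the authors' deposited table. Of the 6 members with a single-copy symbol 5 rose, among them Sp110 at 5.42 ± 0.94, Tmem92 at 5.20 ± 0.90 and Arg2 at 3.88 ± 0.85 in the authors' deposited table. The most abundant of the 6, Zfp809 with a mean of 513, had 0.19 ± 0.45 with adjusted p = 0.908 in the authors' deposited table.

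The list of regulators of MERVL and the 2-cell program, such as the histone chaperone subunits of CAF-1, Kdm1a and the polycomb component Pcgf6, did not rise with it. Of 17 tested members 0 rose and 1 fell, with the same counts when adjusted over the list alone. The one that fell was Chaf1b (chromosome 16, 93883901 to 93906115), a CAF-1 subunit, at -0.93 ± 0.26 with adjusted p = 0.0105 in the authors' deposited table. Zscan4c (chromosome 7, 11005745 to 11010547), also a member, stood at 5.32 ± 2.08 with adjusted p = 0.114 in the authors' deposited table. The list's median was 0.02, at percentile 98.5 of matched random lists, while camera's direction was lower (adjusted p = 0.689).

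Factors that repress TEs, including the DNA methyltransferases and the heterochromatin machinery around Setdb1 and Trim28, rarely passed. Of 36 tested members, 1 rose and 1 fell, also when adjusted over the list alone. Dnmt3a (chromosome 12, 3806007 to 3914443), a de novo DNA methyltransferase, was at 0.85 ± 0.24 with adjusted p = 0.00822 in the authors' deposited table, and the gene that fell was again Chaf1b. The median was 0.01, at percentile 99.9 of matched random lists, while camera's direction was lower (adjusted p = 0.689).

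Germline genes rose in large number. Of 34 tested members, 22 rose and 0 fell; adjusted over the list alone, 25 were higher and 1 lower, with a median of 1.87 (camera, adjusted p = 1.67e-33). Dazl (chromosome 17, 50279395 to 50293636), an RNA-binding protein of germ cells, rose by 3.23 ± 0.40 at a mean of 633 in the authors' deposited table. Tex101 (chromosome 7, 24668007 to 24676675), a protein of the germ cell surface, was at 3.81 ± 0.48 in the authors' deposited table. The authors' deposited table also has Mael at 2.99 ± 0.42, Mov10l1 at 2.39 ± 0.41 and Piwil2 at 1.71 ± 0.45, which passed. Tdrd12 was the member lower when adjusted over the list alone, at -0.67 ± 0.28 with adjusted p = 0.156 over all genes in the authors' deposited table.

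Primitive endoderm genes rose too. Of 20 tested members 9 rose and 1 fell, or 10 higher and 1 lower when adjusted over the list alone, with a median of 1.32 (camera, adjusted p = 2.12e-09). The endocytic adaptor Dab2 (chromosome 15, 6299788 to 6440712) was at 2.75 ± 0.43 and the receptor Cubn (chromosome 2, 13276338 to 13491813) at 3.73 ± 0.61 in the authors' deposited table. Gata6, the transcription factor that specifies this lineage, was at 2.81 ± 0.68 with adjusted p = 0.00138, and the basement membrane collagen Col4a1 at 2.75 ± 0.52, in the authors' deposited table. The lipid carrier Apoe was the member that fell, at -1.74 ± 0.37 and a mean of 29808 in the authors' deposited table. Gata4, with 1.09 ± 0.53 and adjusted p = 0.270 in the authors' deposited table, did not pass.

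Fibroblast markers, included as a check for another cell type, moved in the same direction as these lineage lists. Of 17 tested members 6 rose and 0 fell, and adjusted over the list alone 8 were higher and 1 lower, with a median of 1.25 (camera, adjusted p = 0.0102; 0.0151 to 0.0674 over the alternatives). Col1a2 (chromosome 6, 4504814 to 4541544), a fibrillar collagen, stood at 4.03 ± 0.76 and a mean of only 41.2, and the surface antigen Thy1 (chromosome 9, 44043384 to 44048579) at 1.25 ± 0.34, in the authors' deposited table. Abundant mesenchymal transcripts did not pass: Vim had -0.48 ± 0.25 with adjusted p = 0.333 and Timp1 -0.67 ± 0.36 with adjusted p = 0.359 in the authors' deposited table.

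HOX genes and their cofactors, which pattern the body axis, were higher as a group. Of 19 tested members 3 rose and 0 fell, and 6 were higher when adjusted over the list alone, with a median of 1.42 (camera, adjusted p = 0.000169). The cofactor Meis2 (chromosome 2, 115863064 to 116065839) was at 2.35 ± 0.57 and Hoxd1 (chromosome 2, 74762980 to 74765142) at 2.60 ± 0.79 in the authors' deposited table. The mesoderm list, with 17 tested members, had 1 rise and 0 falls, also when adjusted over the list alone, and a median of 0.64 (camera, adjusted p = 0.0255; 0.00685 to 0.211 over the alternatives). Its member that rose was Kdr (chromosome 5, 75932827 to 75978458), the VEGF receptor of blood and vessel precursors, at 2.19 ± 0.61 with adjusted p = 0.00820, whereas T (chromosome 17, 8434423 to 8442496), or Brachyury, had 2.44 ± 0.92 with adjusted p = 0.0939, both in the authors' deposited table. Fibroblast markers, with their median of 1.25, were higher beside both lists.

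Trophectoderm genes split. Of 18 tested members 3 rose and 1 fell, also when adjusted over the list alone, with a median of 0.74 where the highest of 10000 matched random lists reached 0.72, while camera missed the threshold (adjusted p = 0.0834; 0.0457 on ranks, 0.122 to 0.203 over the other alternatives). Elf5 (chromosome 2, 103411688 to 103450989), a trophoblast transcription factor, was at least 29.1-fold higher, counting WT at a floor of 3 reads over the group since its fitted WT level was that of no reads; its adjusted p was 8.97e-05 at a mean of 14.7 in the authors' deposited table. The bound for Elf5 leaves out the error of its Dot1l KO level. The keratin Krt8 was at 0.99 ± 0.29 with adjusted p = 0.0165 in the authors' deposited table. Fgfr2 (chromosome 7, 130162451 to 133123350), the FGF receptor of trophoblast progenitors, fell by 2.50 ± 0.37, adjusted p = 3.30e-09, per the authors' deposited table. Neuroectoderm genes had 12 tested members with 0 rises and 1 fall, also when adjusted over the list alone, the fall being Pax6. Neurod1 (chromosome 2, 79452521 to 79456751) had -1.20 ± 0.48 with adjusted p = 0.122 in the authors' deposited table, and the list's median of 0.21 was positive while camera's direction was lower (adjusted p = 0.322).

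Few genes of the naive pluripotency network passed, and its central factors did not. Of 26 naive pluripotency genes 1 rose and 2 fell, also when adjusted over the list alone, with a median of -0.25 (camera, lower, adjusted p = 0.0904). Dppa3 (chromosome 6, 122626410 to 122630272), which protects methylation in the early embryo and marks naive cells, fell by 2.17 ± 0.38, adjusted p = 2.21e-06, and the orphan receptor Nr0b1 was at -1.13 ± 0.38, in the authors' deposited table. Tbx3 (chromosome 5, 119670669 to 119684724), a T-box factor of naive cells, was at 1.24 ± 0.36 with adjusted p = 0.0127 in the authors' deposited table. For the central factors the authors' deposited table gives Pou5f1 -0.38 ± 0.34, Sox2 -0.08 ± 0.23 and Nanog 0.30 ± 0.26, with adjusted p of 0.662, 0.923 and 0.653.

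In the primed epiblast list, 3 of 17 tested members rose and 0 fell, also when adjusted over the list alone. Lef1 (chromosome 3, 131110471 to 131224356), a Wnt effector, rose by 2.46 ± 0.43 with adjusted p = 1.61e-06, and Otx2 (chromosome 14, 48657677 to 48673819), an early driver of the primed state, rose by between 1.05 and 2.94 (95% interval of the log2 fold change) with adjusted p = 0.00142, in the authors' deposited table. The other one was Dnmt3a. The list's median was slightly below 0 while camera's direction was higher (adjusted p = 0.207).

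**Figure D2:**
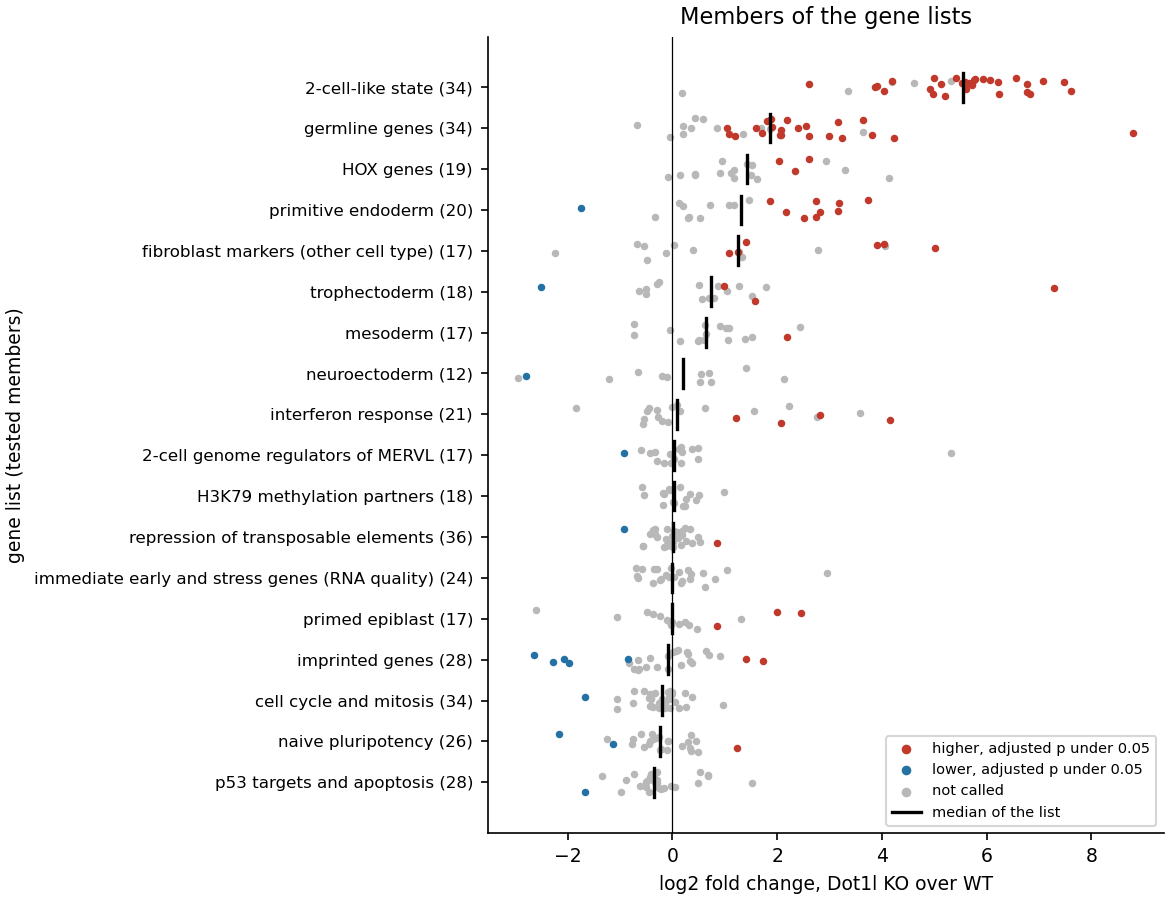
Log2 fold change (Dot1l KO over WT, authors' deposited table) of every tested member of the 18 gene lists with tested members, 1 point per gene, coloured by call, with the median of each list marked. The 2-cell-like list has a median of 5.56, germline genes 1.87, HOX genes 1.42, primitive endoderm 1.32 and fibroblast markers 1.25, and H3K79 methylation partners 0.02.

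Targets of p53 and apoptosis genes were lower as a group, although single members hardly passed. Of 28 tested members 0 rose and 1 fell, and adjusted over the list alone 1 was higher and 2 lower, with a median of -0.34 (camera, adjusted p = 0.0114; 0.00530 to 0.136 over the alternatives). The fall was Ccnd2 (chromosome 6, 127125162 to 127152193), cyclin D2, which drives entry into S phase, at -1.68 ± 0.39 with adjusted p = 0.000672 in the authors' deposited table. The caspase gene Casp8 (chromosome 1, 58795374 to 58847503) had 1.52 ± 0.52 with adjusted p = 0.0516 in the authors' deposited table. The cell cycle list had 34 tested members, 0 rises and 1 fall, again Ccnd2 and also when adjusted over the list alone, with a median of -0.20 at percentile 37.1 of matched random lists (camera, lower, adjusted p = 0.00959; 0.00530 to 0.257 over the alternatives). Cdk6 (chromosome 5, 3341485 to 3531008), a partner kinase of cyclin D2, had -1.06 ± 0.39 with adjusted p = 0.0799 in the authors' deposited table. Both lists hold mainly abundant genes. In the highest of 20 bins of mean count the median log2 fold change of all genes was -0.20. The cell cycle list had a median mean count of 7347, in that highest bin. The p53 list had a median mean count of 1985, in a bin whose median was -0.22. Its median of -0.34 lay at percentile 1.21 of matched random lists, whose median was -0.16.

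A few interferon genes rose. Of 21 tested members 4 rose and 0 fell, and 6 were higher when adjusted over the list alone, with a median of 0.09 (camera, adjusted p = 0.127). The chemokine Cxcl10 (chromosome 5, 92346638 to 92348889) was at 2.81 ± 0.63 with adjusted p = 0.000366 and the antiviral GTPase Mx1 (chromosome 16, 97447035 to 97462907) at 4.15 ± 1.20 with adjusted p = 0.0129 and a mean of 9.39, in the authors' deposited table. Immediate early and stress genes, a sign of RNA quality and handling, had 24 tested members and 0 calls by DESeq2, also when adjusted over the list alone, with 2 higher and 1 lower at an unadjusted p under 0.05. Their median was slightly below 0 with camera's direction lower (adjusted p = 0.914), and the lowest p-values were those of Asns (chromosome 6, 7675169 to 7693254), 0.58 ± 0.25 with adjusted p = 0.193, and Atf3 (chromosome 1, 191170296 to 191218039), 1.05 ± 0.50 with adjusted p = 0.247, in the authors' deposited table. Of the 15 mitochondrial transcripts listed, 0 were in the gene table.

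Among imprinted genes, the maternally expressed RNAs of the Dlk1 to Dio3 domain on chromosome 12 fell. Of 28 tested members of the list 2 rose and 5 fell, also when adjusted over the list alone, with a median of -0.08 (camera, lower, adjusted p = 0.0194; 0.0649 to 0.336 over the alternatives). Meg3 (109541001 to 109571726) fell by 2.07 ± 0.30 at a mean of 10159, Rian (109603940 to 109661716) by 1.98 ± 0.26 at a mean of 9228 and Mirg (109729764 to 109749460) by 2.65 ± 0.53, in the authors' deposited table. Rtl1 (109589193 to 109600330), a paternally expressed gene derived from a retrotransposon, fell by 2.29 ± 0.48 in the authors' deposited table; a maternal transcript runs antisense to it and whether counting used strand is not stated, so its value is uncertain. Of the 14 genes from Dlk1 to Dio3, 4 fell and 1 rose, Dio3 (110279068 to 110281097) at 1.83 ± 0.57 with adjusted p = 0.0259 in the authors' deposited table. Dlk1, at the other end, had -0.64 ± 0.54 with adjusted p = 0.641 in the authors' deposited table, and of the 35 genes outside the domain and within 1 Mb of its ends 0 rose and 1 fell. This was Mok (110807798 to 110840939), a protein kinase gene named after its value was seen, at -1.52 ± 0.34 with adjusted p = 0.000359 in the authors' deposited table. Outside this domain, the authors' deposited table has Plagl1 at 1.73 ± 0.32, Grb10 at 1.40 ± 0.46 and Impact at -0.84 ± 0.28, all past the threshold.

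**Figure D3:**
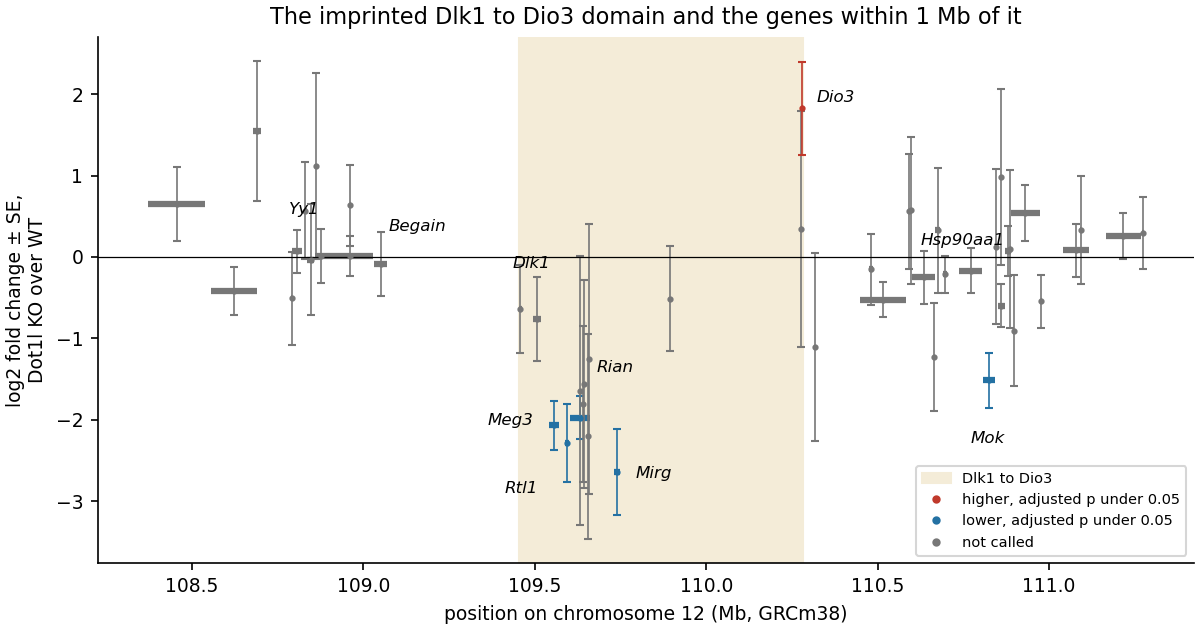
Log2 fold change with its SE (authors' deposited table) of genes on chromosome 12 by position in GRCm38, which is mm10 (Mb), for the Dlk1 to Dio3 domain, shaded, and the genes within 1 Mb of its ends, coloured by call. Meg3, Rian, Mirg and Rtl1 lie between -2.65 and -1.98, and of 35 flanking genes 1 was called, Mok at -1.52.

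At the level of TE subfamilies, few differed. MERVL, the endogenous retrovirus of the 2-cell embryo, rose in both its internal part MERVL-int and its long terminal repeat (LTR) MT2_Mm, and IAPEy-int, a relative of the IAP elements, rose as well. The LTR of the early transposons, RLTRETN_Mm, fell. Of 938 subfamilies 6 were higher and 1 lower at an adjusted p under 0.05, and 18 and 31 without adjustment.

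MERVL-int was at 1.96 ± 0.38, or 3.88-fold, with adjusted p = 0.000107 and a mean of 11376, and MT2_Mm at 1.64 ± 0.41 with adjusted p = 0.00979, in the authors' deposited table. The authors' deposited table has IAPEy-int at 2.95 ± 0.43 with adjusted p = 6.11e-09 and a mean of 101, RLTR45-int at 1.40 ± 0.39 with adjusted p = 0.0453, and LTR31, named after its value was seen, at 1.19 ± 0.30. MamGyp-int, with a mean of 10.3 and adjusted p = 0.000825 in the authors' deposited table, was at least 20.4-fold higher, counting WT at a floor of 3 reads over the group. This bound leaves out the error of its Dot1l KO level. RLTRETN_Mm fell by 2.06 ± 0.48 with adjusted p = 0.00356 in the authors' deposited table.

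Other retrotransposons that are silenced in stem cells did not pass. The authors' deposited table has IAPEz-int at -0.61 ± 0.26 with adjusted p = 0.642, MMERVK10C-int at 0.24 ± 0.22, and the young LINE-1 subfamilies L1Md_A at 0.08 ± 0.57 and L1Md_T at -0.29 ± 0.53, the last 3 with adjusted p = 0.996. All of these elements are repeated many times, and how reads mapping to several copies were counted is not stated.

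By list, the 8 MERVL elements had 2 rises and 0 falls, also when adjusted over the list alone, with a median of 0.14 (camera, higher, adjusted p = 0.000370; 3.38e-06 to 0.0708 over the alternatives). The 5 elements of MusD and the early transposons (ETn) had 0 rises and 1 fall, or 4 falls when adjusted over the list alone, with a median of -0.75 (camera, lower, adjusted p = 4.87e-06). Their most abundant member was MMETn-int, at -0.82 ± 0.25 with adjusted p = 0.0927 and a mean of 70433 in the authors' deposited table. The 18 IAP elements had 1 rise and 0 falls, also when adjusted over the list alone, and a median of 0.01 (camera, adjusted p = 0.572).

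The remaining 6 TE lists had 0 calls by DESeq2 over all subfamilies. For the 12 elements of MMERGLN and RLTR1 the median was -0.64 (camera, lower, adjusted p = 0.0201; 0.0389 to 0.0600 over the alternatives), with 3 lower at an unadjusted p under 0.05 and 0 when adjusted over the list alone. The 15 SINE B1 and B2 elements had a median of -0.19 (camera, lower, adjusted p = 0.000272; 1.46e-05 to 0.360 over the alternatives), with 0 at an unadjusted p under 0.05 and 0 when adjusted over the list alone; random lists matched on mean count had the same median of -0.19. Those random lists were drawn from bins that hold the SINE elements themselves, and their median is the value of a member. The comparison therefore cannot tell whether the SINE elements differ from other elements as abundant. MMERVK10C and RLTR10, with 10 elements, had a median of -0.01 (camera, adjusted p = 0.902), with 1 lower at an unadjusted p under 0.05, which passed when adjusted over the list alone. Young L1 had 12 elements and a median of -0.26 (camera, adjusted p = 0.638), and MaLR and MT had 13 elements and a median of -0.12 (camera, lower, adjusted p = 0.119; 0.0454 on ranks, 0.212 to 0.963 over the other alternatives); in each, 0 had an unadjusted p under 0.05 and 0 passed when adjusted over the list alone. The 4 satellites had a median of -0.40 (camera, adjusted p = 0.0978), with 2 lower at an unadjusted p under 0.05 and 0 when adjusted over the list alone.

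**Figure D4:**
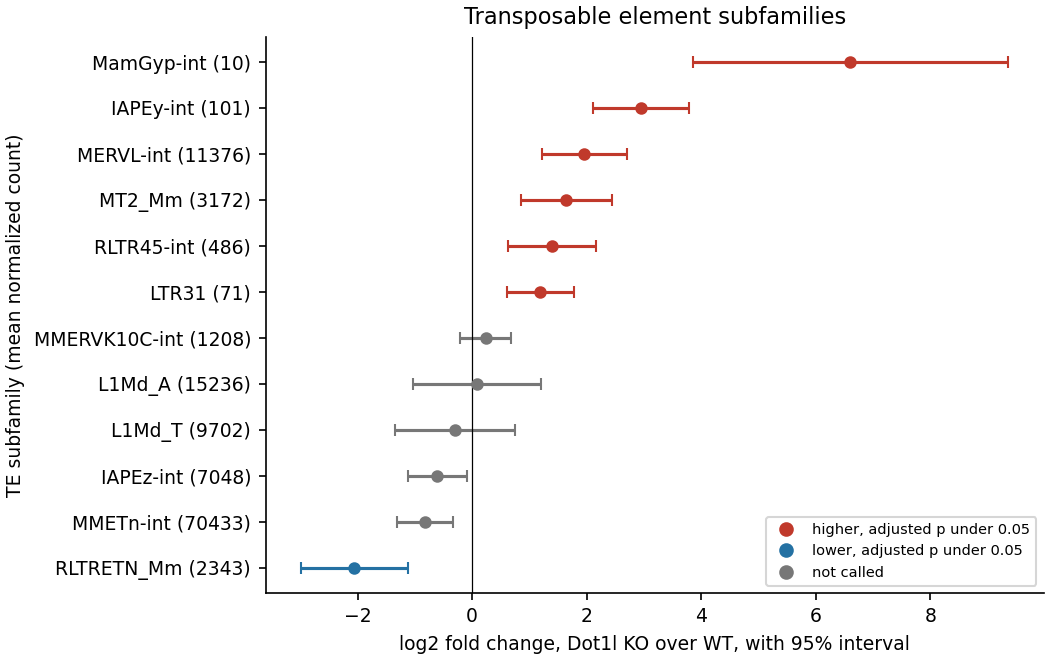
Log2 fold change (Dot1l KO over WT, authors' deposited table) with its 95% interval for the 7 called TE subfamilies, in colour, and 5 others in grey, with mean normalized counts beside the names. MERVL-int at 1.96 and MT2_Mm at 1.64 are the most abundant of the 6 that rose, and RLTRETN_Mm at -2.06 is the one that fell.

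Among single TE copies, MERVL made up most of the rises and the early transposon family most of the falls. Of 349 MERVL-int copies 140 rose and 0 fell, and 29 of 110 MT2_Mm copies rose. Of 169 MMETn-int copies 22 fell, as did 9 of 40 RLTRETN_Mm copies and 7 of 29 RLTR13G copies. Over all 26255 copies, 230 were higher and 60 lower at an adjusted p under 0.05, and 755 and 476 without adjustment.

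The MERVL-int copies had a median log2 fold change of 4.08, or 3.71 with the 60 copies without WT reads at their bound, and 339 of the 349 were positive. The lowest mean over both groups among copies was 3.61, so a copy can be present through its Dot1l KO reads alone. This can raise the median and the shares of positive and called copies above those of all MERVL-int copies. The subfamily as a whole was at 1.96. The share of called copies was larger than among all other copies, of which 90 of 25906 rose (Fisher's exact test, two-sided, adjusted p = 3.33e-209); copies of a subfamily are not independent replicates. The test was run for rises and for falls on all 425 subfamilies with at least 5 copies, whatever their calls, and adjusted over both. It found more rises than among other copies in 4 of them, MERVL-int, MT2_Mm with a median of 2.09 (adjusted p = 2.49e-32), RLTR45-int with 8 of 21 and MT2B1 with 5 of 50. Fewer rises were found in 2, the SINEs B3 with 1 of 1469 and ID_B1 with 0 of 1193 (adjusted p = 0.00431 for each in the same exact test). The copies they were compared with include the 140 MERVL-int and 29 MT2_Mm rises, which lift that share. Whether these 2 SINEs have fewer rises than copies outside MERVL was not tested. More falls were found in 3, with adjusted p = 4.88e-31 for MMETn-int, 4.99e-14 for RLTRETN_Mm and 5.78e-11 for RLTR13G in the same exact test, whose medians were -0.79, -2.97 and -2.08. The LTR class held 209 of the 230 rises and 46 of the 60 falls.

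By the rule on effect size among copies past the threshold with a mean count of at least 50, 3 copies were named for rises. MERVL-int_dup1708 was at least 142-fold higher, counting WT at a floor of 3 reads over the group, with a mean of 71.2 and adjusted p = 6.60e-07 in the authors' deposited table. This bound leaves out the error of its Dot1l KO level. MT2_Mm_dup1684 rose by 6.71 ± 1.14 and MERVL-int_dup1872 by 5.98 ± 1.13 in the authors' deposited table. Among falls past the threshold, L1_Mus4_dup4514 was at -6.28 ± 1.29, LTRIS2_dup184 at -5.92 ± 1.23 and RLTR13G_dup863 at -5.36 ± 1.06 in the authors' deposited table. The names carry no coordinates, so the place of a copy in the genome is not given here.

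IAPEz-int had 187 copies and 0 calls by DESeq2, with 4 higher and 8 lower at an unadjusted p under 0.05, and a median of -0.41. L1Md_A had 490 copies with 0 rises, 1 fall and a median of 0.61, with 15 higher and 7 lower at an unadjusted p under 0.05. L1Md_T had 224 copies with 0 calls, 3 higher and 9 lower at an unadjusted p under 0.05. Most rises were near the limit of detection: for 167 of the 230 rises the implied mean of the WT group was under 1 normalized count. With an implied mean of at least 1 in the lower group, 50 copies were higher and 30 lower, and at a mean count of at least 50, 18 were higher and 36 lower.

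**Figure D5:**
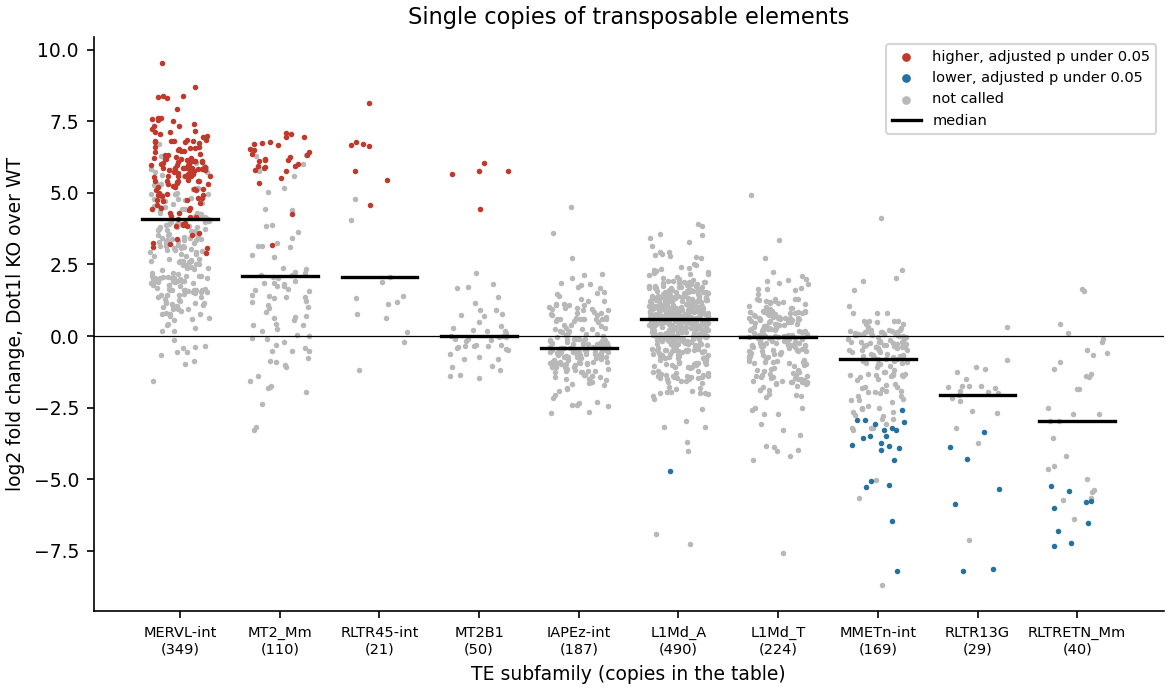
Log2 fold change (Dot1l KO over WT, authors' deposited table) of every single copy of 10 TE subfamilies, 1 point per copy, coloured by call, with the median of each subfamily marked. MERVL-int has a median of 4.08 over 349 copies, MMETn-int -0.79 over 169 and IAPEz-int -0.41 over 187. The lowest mean over both groups among copies was 3.61, and the MERVL-int subfamily as a whole was at 1.96.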

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

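No paired analysis was possible because the tables carry no per-sample values. For the same reason the planned replicate block, DESeq2 refit, upper-quartile or quantile normalization, missing filter, other pseudocount, TMM within the TE tables, leaving out each sample, rotation test with the block, camera with an estimated correlation and other splits of the samples were not run. Of the other settings, the threshold of 0.01 and the fold minimum had been chosen in advance, and all others were chosen after seeing the data. Under every alternative run in which they had a value, 33 of the 45 named genes, 9 of the 10 named TE subfamilies and all 6 named copies kept their direction and their side of the threshold, as did 9 of 18 gene lists and 3 of 9 TE lists. Among named genes, 29 results fell short of the threshold, over 11 genes, mostly under Bonferroni or scaling of the statistics, and 1 passed it. RLTR45-int fell short at 0.01 and under Bonferroni.

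Genes higher and lower numbered 661 and 106 at 0.01, 418 and 48 with statistics scaled by their interquartile range, and 275 and 34 under Bonferroni. A mean count of at least 50 left 517 higher, and centring within bins gave 159 lower, of which 132 were among the 244. For subfamilies, 2 were lower at a mean count of at least 50 and 3 with scaled statistics, which tested fewer entries or widened the statistics; the share of higher among calls was 71.4% and 66.7% there, against 85.7%. Copies higher and lower numbered 140 and 38 at 0.01, 18 and 36 at a mean count of at least 50, 488 and 210 with scaled statistics, 45 and 18 under Bonferroni, and 50 and 30 with an implied lower mean of at least 1. A stricter threshold and Bonferroni lower counts by construction. The filter on mean count removes entries and adjusts over fewer, so it also adds calls: 14 of its 18 higher and 30 of its 36 lower copies were among the calls without it. The scaling narrows the gene statistics (ratio 1.30) and widens those of copies (0.762).

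The number of gene lists called was 9, with 4 at a preset correlation of 0.05 and 5 after centring within bins; the cause of the latter was not tested. On ranks the trophectoderm list (0.0457, against 0.0834) and the MaLR and MT list (0.0454, against 0.119) passed, and the cause was not tested. Dot1l went to 0.0115 after centring within bins, with adjusted p = 0.995. The direction of some uncalled lists reversed: stress genes with adjusted p = 0.998 on ranks and 0.690 after centring, TE repression 0.211 and MERVL regulators 0.387 after centring, MMERVK10C and RLTR10 0.954 on ranks and 0.963 after centring, and young L1 0.963 after centring; the cause was not tested. Weak genes and copies rest on few reads: 104 genes and 138 copies had a WT level of no reads, against 0 and 21 in Dot1l KO; whether these are silent or were missed at this depth was not tested.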

Other observations

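Several gene families that share a symbol stem held many rises in Dot1l KO, some of them through members of the fixed lists. These families, the chromosome windows, the X and Y chromosomes, the ribosomal protein genes and the single genes named were examined only after the fold changes were seen. Of 532 groups of genes that share a symbol stem, 6 held more rises than the rest by a two-sided Fisher's exact test. Near-identical copies in such groups and in the chromosome windows can share reads, and the test counts them as independent genes. Of 11 Xlr genes 10 rose (adjusted p = 2.00e-09), of 37 collagen genes (Col) 13 (1.50e-05), of 5 ferritin-like Fthl genes 5 (0.000152), of 20 Tex genes, expressed in testis, 8 (0.00120), of 12 Rhox homeobox genes 6 (0.00338) and of 21 Zscan genes 7 (0.0128). Of these rises, 7 of the collagen genes, 3 of Tex and 3 of Zscan are members of the fixed lists. With all list members left out, the same exact test kept Xlr (adjusted p = 1.02e-09), Fthl (0.000159) and Rhox (0.00377), while Tex with 5 of 16 (0.107), collagen with 6 of 27 (0.158) and Zscan with 4 of 15 (0.328) did not pass. The convertases named Pcsk held 3 falls of 8 (0.0156). The families include X-linked germ cell genes, such as Rhox13 at 3.27 ± 0.42 and Fthl17d at 5.50 ± 0.86 in the authors' deposited table, while the placental Rhox5 stood at -1.76 ± 0.50 there. The genes with the lowest p-values included the testis tubulins Tuba3b at 5.62 ± 0.42 and Tuba3a at 3.25 ± 0.28, the meiotic chaperone Fkbp6 at 4.55 ± 0.36 and Ctcfl, the testis paralog of CTCF, at 3.51 ± 0.43, in the authors' deposited table.

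On the X chromosome, without Xlr genes, 91 of 678 genes rose (13.4%), and 940 of 18869 on autosomes (4.98%); Fisher's exact test of that X-linked share against all other genes gave p = 3.21e-16, two-sided. Over the 20 chromosomes tested, each against all other genes, the share of rises differed on the X with its Xlr genes (101 of 689, adjusted p = 3.91e-19) and, the other way, on chromosome 17 (21 of 988, adjusted p = 8.39e-06) by the same exact test. Of 1306 windows of 1 Mb, those with the lowest p for an excess of rises were the Xlr window on chromosome X with 16 of 36, a window on chromosome 12 (87021340 to 87988959) with 14 of 28, the next one (88011848 to 90334935) with 8 of 10, the Zscan4 window on chromosome 7 with 7 of 9 and the Tdpoz window on chromosome 3 with 7 of 11 (Fisher's exact test, two-sided, adjusted p from 2.67e-08 to 0.000172). Falls clustered by the same exact test in the Meg3 window with 4 of 13 (adjusted p = 0.00504) and on chromosome 3 (95006590 to 96058466) with 6 of 51 (adjusted p = 0.0104), among them Mindy1 and Prune1. Median log2 fold changes by chromosome lay between -0.14 on 17 and 0.13 on 13 over all genes, and between -0.21 on 17 and just under 0 on 13 among genes with a mean count of at least 50. Other genes that fell included the guidance cue Ntn1 at -2.03 ± 0.29, the Hedgehog effector Gli1 at -1.75 ± 0.29, the DNA sensor Aim2 at -2.17 ± 0.24 and the RNA helicase Mov10 at -1.32 ± 0.28, in the authors' deposited table. Of 84 ribosomal protein genes 0 were called by DESeq2, with 0 higher and 1 lower at an unadjusted p under 0.05, yet 80 were negative with a median of -0.59, under the lowest of 10000 matched random lists (-0.39). After centring within bins their median was -0.39. Of 13 Y-linked genes 3 rose and 0 fell: Kdm5d was at 5.42 ± 0.79, Zfy1 at 2.94 ± 0.82 and Uba1y at 1.33 ± 0.42, while Uty had -0.86 ± 0.49 and Ddx3y -0.72 ± 0.43, which did not pass, in the authors' deposited table. The 3 that rose are neighbours among the 13, with the lowest positions, from 725128 to 956786. Whether the samples differ in this stretch of the Y chromosome was not tested. Among copies, 6 had an absolute log2 fold change above 15, of which 4 have no p, and 136 share all values with another copy.

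For the patterns weighed next, the tests of a shift as the whole cause, of wide statistics, of depth, of LTR elements in general and as a class, of the flanks of the whole domain and of imprinted genes in general were chosen after the results they measure were seen.

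The excess of rises among weakly expressed genes may be partly a shift with mean count: after centring within bins 70.1% of the rises were still called, which neither excludes nor shows a share of the shift in the excess. As the whole cause the shift is argued against, since after centring 592 of the calls below the median mean count were higher and 85 lower, that is 87.4% higher (exact 95% interval 84.7 to 89.8). Wide statistics, which add as many falls as rises, are argued against as the whole cause as well: with the centred statistics of these genes also scaled by their interquartile range, 202 were higher and 19 lower, that is 91.4% higher (exact 95% interval 86.9 to 94.7). For TE copies, a difference in depth is argued against by the steps between their lowest fitted levels. There, 1 read stood for 1.03 times the level in WT that it did in Dot1l KO (95% bootstrap interval 1.00 to 1.05, from 205 and 53 copies). Whether the genes had the same size factors is not stated, so these steps cannot decide on depth for the genes. Genotype, a difference between clones and, for the genes, a difference in depth stay open, and none of them was tested on the genes.

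For the rise of the 2-cell-like list and of MERVL, a shift with mean count is argued against by the list's median of 5.56, where the highest of 10000 matched lists had 0.94. A release of LTR elements in general is argued against by IAPEz-int and MMERVK10C-int, whose higher upper 95% bound was 0.68, under the lower bound of 1.22 for MERVL-int, and by the 554 LTR subfamilies outside the MERVL list, whose median was -0.0358 (95% bootstrap interval -0.07 to -0.01). Of these 554, IAPEy-int, RLTR45-int, MamGyp-int and LTR31 rose and RLTRETN_Mm fell. The median of the 554 speaks only to a rise of most of them, and its interval resamples subfamilies, not samples. A release of single others, or of a minority of them, beside MERVL is not excluded. Among the genes of the list, reads shared between copies are argued against by the 6 members with a single-copy symbol. Their median was 4.54 (95% bootstrap interval 1.39 to 6.45), although Zfp809 among them did not pass. Single copies were judged by symbol only, and Zfp352 entered at its fitted value without WT reads. Whether the sequences of the 6 are unique was not tested, nor was sharing of reads among MERVL copies. A hypothesis that remains is that more cells of the Dot1l KO cultures were in the 2-cell-like state, or that each cell had more of these transcripts, which bulk RNA cannot separate; the sign itself was read from MERVL.

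The fall of Meg3, Rian, Mirg and Rtl1 is not that of a lost stretch that takes in the flanks, which would need flanking genes near -1: the 21 genes outside the domain and within 1 Mb of the 4 had a median of -0.0309 (95% bootstrap interval -0.21 to 0.33), and the 35 within 1 Mb of the domain's ends 0.0679 (-0.17 to 0.30). Of these 35 only Mok fell, at -1.52 in the authors' deposited table, and a loss of a shorter stretch was not tested. Nor did imprinted genes in general fall, since the 23 outside the domain had a median of 0.0752 (-0.29 to 0.30), against -2.18 for the 4. A change of imprinting at this domain may accompany the genotype or may mark a clone, since silencing of Meg3 is known to vary between embryonic stem cell lines. The rise of Dio3 beside the falls goes with a switch of this kind as a hypothesis, but Dlk1 did not pass, the fall of the paternally expressed Rtl1 runs against it unless its reads came from the antisense maternal transcript, and neither alleles nor DNA methylation were measured here.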
